A study of Mus musculus with 2 samples.

How the data were processed

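RNA was sequenced from RANKL-treated cultures of mouse bone marrow-derived cells, with 1 control library and 1 MMP9 knockout library, so each group had n = 1. Per the labels, marrow of C57BL/6 mice aged 6 to 8 weeks was grown in medium with 10% serum and M-CSF at 5 ng/ml, the non-adherent cells were then kept in M-CSF at 30 ng/ml for 3 days, and the adherent macrophages received RANKL for 3 days. Polyadenylated RNA was sequenced on an Illumina instrument, per the labels. The column headings of the deposited table also carry the letters "NCsh" for the control and "sh" for the knockout. The labels do not explain these letters, and whether Mmp9 was deleted or silenced is not given in the sources used here; the name knockout follows the labels. The columns were matched to the groups by the genotype and treatment in their headings.

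Reads were aligned with TopHat and the mouse build was mm9, per the submitters' processing notes. The aligner version, the counting program, the gene annotation, the use of strand and the normalisation method are not given in the sources used here. The authors deposited 1 table of log2 values for 26037 genes. The table is titled as normalised RPKM, but the values did not behave as such: after conversion from log2 they lay on whole multiples of 1 step per library, and that step was the same for genes of any length. They were therefore treated as log2 of read counts multiplied by 1 factor per library, without division by gene length, and the converted values are called normalised read counts. A gene with no read carried the log2 of 0.9 of the step, and it was set to 0 here. The step was 0.0248 in the control and 0.0238 in the knockout. Which total the authors divided by is not known. In the control 99.99% of values, and in the knockout 99.99%, lay within 0.05 of a whole read. The reads so obtained summed to 20678441 in the control and 17741432 in the knockout. A count of 0 allows a normalised read count of up to 0.0745 in the control and 0.0713 in the knockout, taking 3 reads as the limit.

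The comparison used log2 of the knockout value plus a pseudocount of 1 over the control value plus 1, which understates the difference for genes with low values. Genes with a mean of at least 1 over both libraries were compared, which left 11126 genes. A gene counted as higher or lower when it differed by at least 2-fold on this scale. These thresholds had been set for RPKM and were applied unchanged to the normalised read counts. With 1 library per group no test between genotypes was possible, so no p-value is given and every difference lacks a replicate check. Fold differences were computed from the values without a pseudocount, with exact 95% intervals from the read numbers. Counts of genes past 2-fold use the pseudocount scale, so a gene counted as within 2-fold can have a fold above 2. Where 1 library had no read the fold was computed against 3 reads and is a lower bound. These intervals and limits cover counting error only and treat reads as independent. Reads without molecular identifiers are not independent molecules, so the intervals are likely too narrow even for counting error.

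The named genes are Mmp9, the 12 genes with the largest and the 12 with the smallest log2 ratio among genes with a mean of at least 5 (clone names, predicted genes and small RNAs left out), and in each of 39 gene lists the first 3 members and the 4 compared members that differed most. The lists hold 936 entries and cover osteoclast and macrophage biology, other cell types, metabolism, chromatin and technical controls. For each list with at least 3 compared members, the median log2 ratio was placed among 10000 random gene lists of the same size, matched in 20 bins of mean expression, as a description of these 2 libraries. A bootstrap interval of a list median holds the 2.5 to 97.5 percentiles of 2000 draws of its members with replacement. It describes spread among the chosen genes, which are not independent, and not variation between cultures. The lists, thresholds, naming rule and processing alternatives, except those named below as added, were chosen before the data were examined. Of the list symbols, 14 had no entry among the genes. GENCODE M21 on GRCm38 gave chromosome, position, biotype, and the GC content and length of the longest transcript by Ensembl identifier, with 23607 genes matched. It is another build than the one used for alignment, so positions are those of GRCm38. GC content and length were known for 96.2% of the compared genes.

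The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, scaling of the knockout to a median log2 ratio of 0, by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed) or to the same sum, the mean in place of the median of a list, and unmatched random lists. Centring of the log2 ratios in bins of GC content, length or both, and lists without members of another list, were added after the data were seen. The planned mean over repeated rows of a symbol was not run because 0 symbols were repeated. The calculation was tested on simulated data with the 26037 genes of the knockout and control comparison. The simulated libraries differed by Poisson counting error only, with no variation between cultures. Of 200 genes given a 4-fold difference 97% passed 2-fold, 0 unchanged genes did, and 95.5% of counting intervals held the true ratio. These values check the calculation and give no rate of false calls between real cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No sequence reads were reprocessed, and genes that share reads with close relatives (the Ifit, Oas, lysozyme, Lilrb and histone families) or overlap a neighbour are uncertain because the handling of such reads is not known.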

Results

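The transcriptome of RANKL-treated cultures was compared between a control and an MMP9 knockout. RANKL is the cytokine that turns bone marrow macrophages into osteoclasts, the multinucleated cells that resorb bone, and MMP9 is a matrix metalloproteinase abundant in osteoclasts. The series concerns proteolysis of histone tails in differentiation, and the comparison asks which transcripts differ between the library labelled MMP9 knockout and the control. Whether Mmp9 was deleted or silenced is open, and "knockout" follows the labels. There was 1 library per genotype, so the differences below have no replicate check and describe these 2 libraries. The control held 20678441 reads in 15744 genes with a read and the knockout 17741432 reads in 15414. Levels are normalised read counts, and intervals in parentheses are 95% intervals for counting error only. Counts of genes past 2-fold use a pseudocount of 1, and printed folds do not.

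Mmp9 itself was 35.99-fold lower in the knockout (30.8 to 42.3), at 139.4 in the control and 3.87 in the knockout. These levels rest on 5609 and 163 reads, so 2.78% of the control level was left. Mmp9 (ENSMUSG00000017737) lies on the plus strand of chromosome 2, from 164940780 to 164955850 in GRCm38. Its log2 ratio of -4.85 was the 6th lowest of 8900 genes with a mean of at least 5, so 5 genes that were not targeted had a lower ratio. Among these were the osteoclast genes Ctsk and Itgb3, so the low Mmp9 level alone does not establish that Mmp9 was targeted. Among 10 compared metalloproteinases, ADAM proteases and inhibitors, 3 were lower by at least 2-fold (Mmp9, Mmp14 and Timp2) and 2 were higher, among them Adam17 (2.62-fold, 2.47 to 2.77). Timp2, an inhibitor of metalloproteinases, was 3.83 in the control and 0.0238 in the knockout. The median log2 ratio of this group was 0.20 and its mean -0.50, which differ in sign.

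Genes of the mature osteoclast were among those with the lowest ratios. Ctsk, the collagen-degrading cathepsin K, was 87.2-fold lower (83.3 to 91.4), at 3745 in the control and 42.9 in the knockout. Itgb3, the integrin beta chain of the osteoclast attachment zone, was 96.5-fold lower (62.3 to 158), and Oscar, a costimulatory receptor, was 95.9-fold lower (53.4 to 193). Gpnmb was 82.3-fold, Tgm2 82.5-fold, Mst1r 47.5-fold, Cldn11 47.8-fold, Ccr1 31.2-fold and Ckb 28.5-fold lower. At the other end, the inducible nitric oxide synthase gene Nos2 was 0.199 in the control and 81.1 in the knockout, 408-fold higher (207 to 945). The interferon-stimulated genes Rsad2 and Usp18 were 173-fold and 88.5-fold higher, Irg1, which makes itaconate, 113-fold, the chemokine gene Ccl4 66.0-fold, and Ifi44 29.6-fold. Of 11126 compared genes, 445 were higher and 1066 lower by at least 2-fold, so 29.5% of the 1511 genes past 2-fold were higher. The median log2 ratio was -0.16. This split depended on scaling: 565 were higher and 799 lower (41.4% higher) with the median set to 0, a shift of 0.18, 572 and 791 (41.97%) with a trimmed mean, and 674 and 684 (49.6%) with equal sums. Across genes, which are not independent replicates, the log2 ratio had a Spearman rho of -0.31 with transcript GC content and 0.15 with transcript length. Centring in bins of GC content gave 547 higher and 684 lower (44.4%), in bins of length 524 and 746 (41.3%), and in bins of both 537 and 683 (44.02%).

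**Figure D1:**
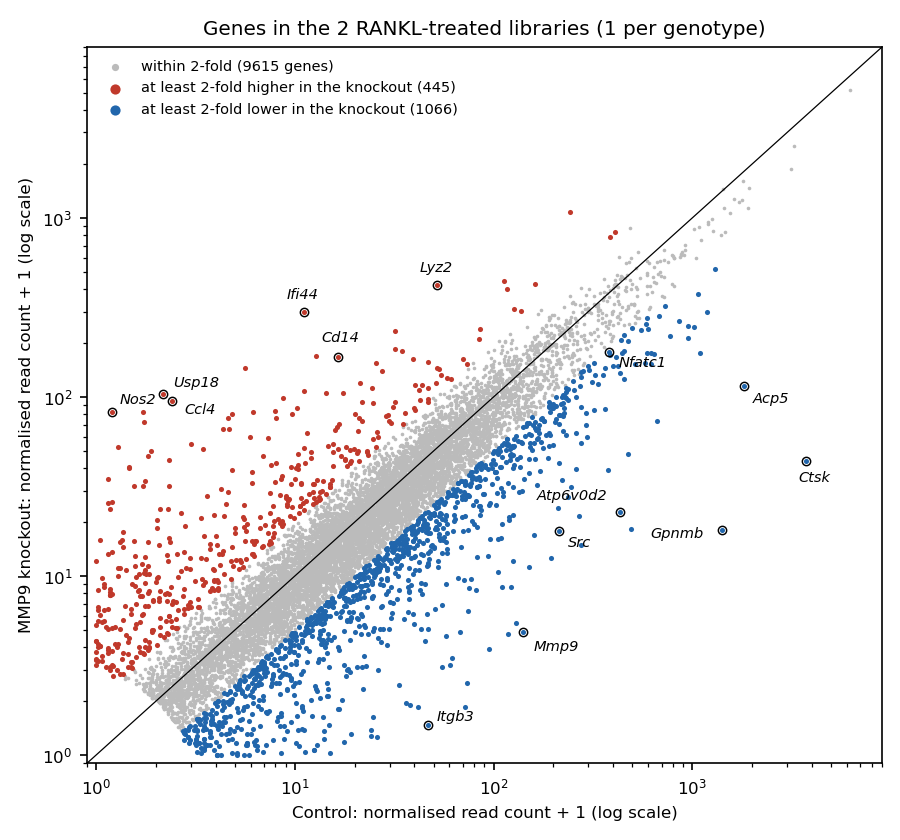
Normalised read count plus 1 of each compared gene in the control (horizontal, log scale) and the MMP9 knockout (vertical, log scale), with 1 library each and the line of equal levels. Red marks the 445 genes at least 2-fold higher and blue the 1066 at least 2-fold lower in the knockout (674 and 684 with equal sums), and named genes are circled.

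Osteoclast differentiation and fusion genes were lower as a group: of 29 compared, 24 were lower by at least 2-fold, 0 were higher and 5 were within 2-fold. Acp5, which encodes tartrate-resistant acid phosphatase, was 16.1-fold lower (15.6 to 16.5), at 1828 and 114. The fusion genes Dcstamp (Tm7sf4 in the table) and Ocstamp (4833422F24Rik) were 5.81-fold and 7.08-fold lower, and the kinase gene Src was 12.6-fold lower. Nfatc1, the transcription factor that drives osteoclast formation, was 2.14-fold lower (2.08 to 2.20), and Tnfrsf11a, the receptor of RANKL, was 128 and 66.0. The list median was -1.88, or -1.72 relative to all compared genes, below each of 10000 random lists. Genes for bone resorption, 10 of which are shared with other lists, gave 18 lower and 0 higher of 23, with a median of -1.88, below each random list. Both medians are the value of Itgav, a member of both lists that was named after its value was seen. The resorption list is therefore not a separate result. The chloride channel gene Clcn7, in the resorption list, was 6.60-fold lower.

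Subunits of the proton pump that acidifies the resorption space and lysosomes were lower too, 14 of 19 by at least 2-fold, with a median of -1.47. Atp6v0d2 was 20.02-fold lower (18.7 to 21.4), Atp6v1g1 4.53-fold and Atp6v1b2 3.99-fold, while Atp6v0a1 was 24.4 and 38.9. Of 31 cathepsins and lysosomal enzymes 12 were lower and 0 higher on the pseudocount scale, with a median of -0.88. Without a pseudocount Ctsc, just under the threshold at 0.998, was 2.08-fold higher (1.86 to 2.33). Ctse, named after its values were seen, was 1.62 in the control and 3.61 in the knockout. Arsb was 6.72-fold, Hexa 3.83-fold and Psap 3.51-fold lower. Both medians lay below each random list. Podosome and cytoskeletal genes gave 10 lower and 0 higher of 29, with a median of -0.66 at percentile 0.08. Pstpip1 was 8.82-fold, Zyx 4.19-fold and Anxa2 4.05-fold lower. The medians of these lists kept their sign under each scaling and centring tried. The scalings, with a log2 shift of at most 0.29, could not have changed it.

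**Figure D2:**
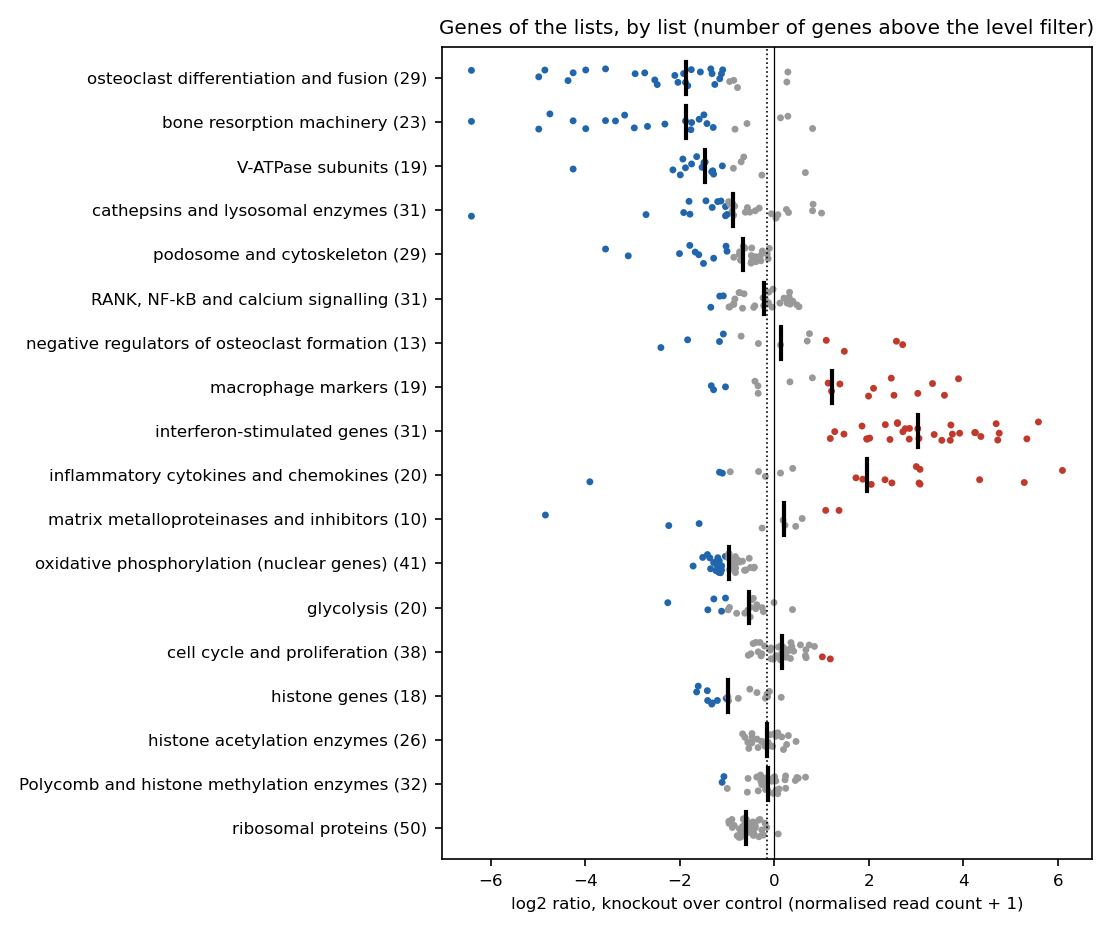
Log2 ratio of knockout over control (horizontal, normalised read count plus 1) for each compared gene of 18 gene lists, with the number of genes in brackets, thick bars at list medians, and the dotted line at the median of all compared genes. Osteoclast and resorption genes lie to the left with medians of -1.88, interferon-stimulated genes to the right at 3.03, and the medians of the signalling, acetylation and Polycomb lists changed sign under other scalings.

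RANK, NF-kB and calcium signalling genes lay near the median of all genes. Of 31 compared, 3 were lower by at least 2-fold and 28 were within 2-fold. The lower ones were the adaptor genes Traf6 (2.62-fold, 2.42 to 2.85) and Tyrobp (2.25-fold) and the NF-kB subunit gene Nfkb2 (2.13-fold). The list median of -0.23 stood at percentile 27.53 of the random lists and turned positive with equal sums. Negative regulators of osteoclast formation went both ways, with 4 higher and 4 lower of 13 and a median of 0.13 at percentile 95.73. The median was 0.41 at percentile 99.95 with a mean level of at least 5, 0.42 at 99.56 after centring by GC content, and 0.74 at 100 without members shared with other lists. The transcription factor gene Irf8 was 12.7-fold higher (8.74 to 19.1) and Socs3 10.6-fold higher, whereas Rcan1 was 3.67-fold lower and Lilrb3 13.1-fold lower.

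Macrophage markers were higher as a group: 11 of 19 were higher by at least 2-fold, 3 were lower and 5 were within 2-fold. The 3 lower ones, named after their values were seen, were Cd68 (150 and 60.9), Sirpa (138 and 54.0) and Sfpi1 (98.4 and 47.5). Emr1, which encodes the F4/80 antigen, was 20.5-fold higher (16.8 to 25.4), Cd14 10.8-fold (9.92 to 11.7) and the lysozyme gene Lyz2 8.34-fold (7.96 to 8.73). Fcgr1, a high-affinity IgG receptor gene, had no read in the control and 11.1 in the knockout, at least 149-fold higher. Members such as Fcgr1 passed the level filter only through the knockout, so the filter set part of the count of higher markers. Csf1r, the M-CSF receptor gene, was 751 in the control and 564 in the knockout. The median was 1.21, or 1.37 relative to all compared genes, above each of 10000 random lists. The list members spread widely, so that the bootstrap interval of the median over members ran from -0.34 to 2.47. That interval does not measure variation between cultures. Without a filter on low values the median was 0.22. Dendritic cell markers gave 1 higher (Ccl22, 11.4-fold) and 2 lower (Itgax, 16.9-fold, and Zbtb46, 3.56-fold) of 3 compared.

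**Figure D3:**
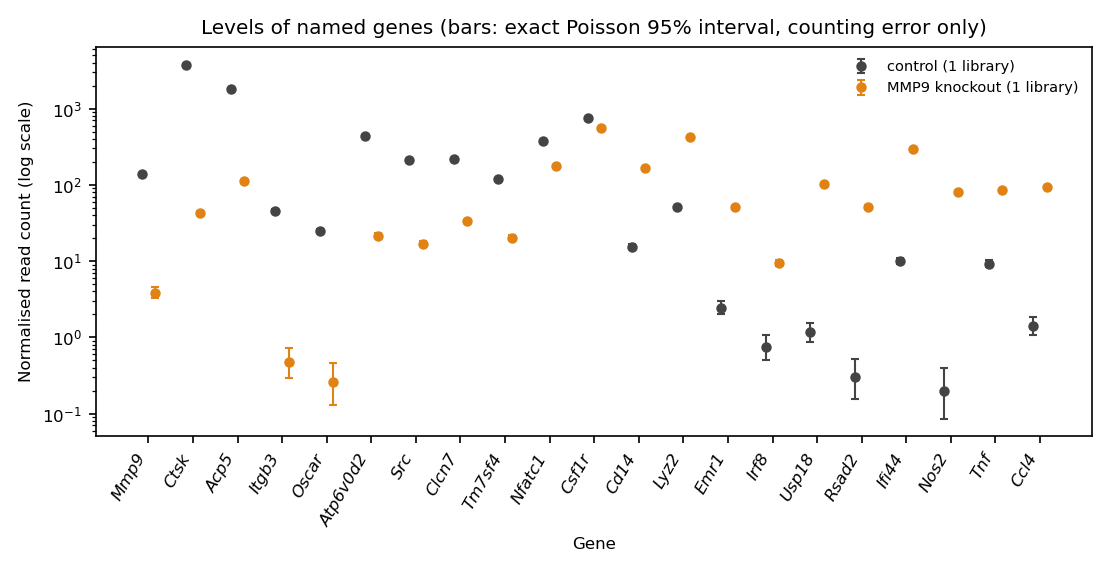
Normalised read count (vertical, log scale) of 21 named genes in the control (grey) and the MMP9 knockout (orange), 1 library each, with bars for exact Poisson 95% intervals that cover counting error only. Ctsk was 3745 and 42.9, Nfatc1 378 and 177, and Nos2 0.199 and 81.1.

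Of the compared interferon-stimulated genes 31 of 31 were higher by at least 2-fold, with a median of 3.03 that lay above each random list. Members low in the control, such as Ifit1, passed the level filter only through the knockout, so the filter set part of this count. Left out by the filter, and named after their values were seen, Mx1, Gbp2, Gbp5 and Cxcl9 did not reach 2-fold on the pseudocount scale, which shrinks low values. Without a pseudocount Mx1 (0.0497 and 0.998), Gbp2 (0.0248 and 0.404) and Gbp5 (0 and 0.879) were higher in the knockout. Cxcl9 had 1 read in the control and 0 in the knockout. Ddx58, which encodes the RNA sensor RIG-I, was 31.3-fold higher (27.02 to 36.4) and Rtp4 55-fold higher. Ifit1 was 0.0497 in the control and 14.9 in the knockout, with a wide interval from 82.6-fold to 2480-fold. Of 20 inflammatory cytokines and chemokines 12 were higher and 3 lower, with a median of 1.96 above each random list (bootstrap interval -0.03 to 3.03). Members such as Nos2, Cxcl2 and Ccl22, each under 1 in the control, passed the filter only through the knockout. The filter therefore set part of this count and percentile too. Without a filter on low values the median was 0.39. Tnf was 9.27-fold higher (8.33 to 10.4) and Cxcl2 131-fold higher (63.5 to 327), whereas Lif was 36.8-fold lower (25.2 to 56.2). Antigen presentation genes gave 4 higher and 2 lower of 14, with a median of 0.19 at percentile 98.8, or 0.12 at 95.06 without shared members and -0.0029 at 81.86 without a filter. Cd86 was 34.9-fold higher and Cd80 3.89-fold lower. Beside these groups, the summed level of 92 markers of granulocytes, stromal, B, T, NK, mast and erythroid cells was 18.8 in the control and 40.1 in the knockout, most of it from Blnk (11.98 and 22.5).

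Genes in the lists of histone acetylation enzymes and of Polycomb and histone methylation enzymes mostly stayed within 2-fold. These lists do not hold every gene that acts on histones, and Kdm3a, in the hypoxia list, was 3.46-fold lower. None of 26 histone acetylation enzymes differed by 2-fold, and Ep300, which encodes the acetyltransferase p300, was 78.4 and 73.7. Their median was -0.17 at percentile 46.83. Of 32 Polycomb and histone methylation enzymes 30 were within 2-fold on the pseudocount scale and 2 were lower. These 2 were the DNA methyltransferase gene Dnmt3a (2.10-fold, 2.05 to 2.16) and Dot1l (2.17-fold, 2.09 to 2.25). Cbx8 fell just short on that scale, at -0.9991, but was 2.89-fold lower (2.06 to 4.13) without a pseudocount. The median of the 32 was -0.13 at percentile 63.84. Both medians changed sign under some scalings, including equal sums. Of 18 histone genes 8 were lower by at least 2-fold, with a list median of -0.98 below each random list, and the split lay by class. The 11 clustered genes named Hist had a median of -1.32 and included the 8 lower ones, among them Hist2h3c1 (3.76-fold) and Hist1h1c (3.28-fold). The 7 variant genes named H2af or H3f3 had a median of -0.16, between -0.52 and 0.14, in a split made after the values were seen. Replication-dependent histone transcripts mostly lack a poly(A) tail, and the libraries were made from polyadenylated RNA.

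All 41 compared oxidative phosphorylation genes had a log2 ratio below 0 with the values as deposited. Of these 19 were lower by at least 2-fold and 22 were within 2-fold, and the median of -0.97 lay below each random list. Ndufb10 was 3.47-fold (3.15 to 3.81), Cox4i1 2.60-fold and Sdha 2.37-fold lower. Glycolysis genes gave 5 lower and 0 higher of 20, with a median of -0.54 at percentile 1.79, and Eno2 was 6.57-fold lower. With centring in bins of GC content the percentile of glycolysis was 7.02. Of 38 cell cycle genes 36 were within 2-fold and 2 were higher, Rrm2 (2.30-fold) and Ccne1 (2.10-fold). Their median was 0.15 at percentile 99.95. The proliferation markers Mki67 and Top2a were 325 and 321, and 199.5 and 222. Ribosomal protein genes had a median of -0.60 at percentile 0.02, and 50 of 50 were within 2-fold.

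Control groups gave the following values. The 28 compared genes near Mmp9 on chromosome 2 had a median of -0.25 at percentile 26.01, which turned positive with equal sums and after centring by GC content, with 1 higher (Cd40, 14.4-fold) and 5 lower, including Pltp (8.97-fold) and Ctsa (2.05-fold). Of 16 housekeeping genes 14 were within 2-fold, with a median of -0.36 at percentile 27.98. Actb was 3120 and 1866, and Hprt was 107.8 and 175. The 4 compared Y-linked genes had a median of 0.23. The 4 compared noncoding RNAs had a median of -0.23, which turned positive with equal sums. Few genes of other cell types reached the level for comparison. The summed levels in control and knockout were 10.1 and 8.93 for monocyte markers, 1.59 and 5.99 for neutrophil markers, 3.01 and 2.19 for stromal markers, and 12.1 and 22.9 for B cell markers. They were 1.69 and 8.41 for T and NK cell markers, 0.248 and 0.475 for mast cell markers, 0.149 and 0.119 for erythroid markers, 48.01 and 1.64 for megakaryocyte markers (which include Itgb3), and 6.34 and 5.89 for endothelial and adipocyte markers.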

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

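The centring in bins of GC content or length and the lists without shared members were chosen after the data were seen. No paired analysis was possible because there was 1 library per group and the labels give no replicate numbers, and for the same reason no library could be left out. The Mmp9 level stayed lower in the knockout under each of the 10 alternatives, with log2 ratios of -5.13 with a pseudocount of 0.1, -4.02 with a pseudocount of 5, -4.62 with equal sums, -4.47 after centring by GC content and -4.54 after centring by GC content and length; the pseudocount acts through the low knockout level by construction. With a pseudocount of 5, which shrinks low genes by construction, 255 genes were higher in the knockout by at least 2-fold and 603 lower. With equal sums 674 were higher and 684 lower, and 684 and 683 were lower after centring by GC content and by GC content and length. Over 13 alternatives the osteoclast list median lay between -2.26 and -1.49 and the resorption list median between -2.34 and -1.60, each below every random list drawn, and the macrophage list median between 0.22 and 1.60, above every random list drawn. A scaling moves the random lists together with the list, so it can hardly change these positions. The bootstrap interval of the macrophage list spans 0, so staying inside it says nothing about stability. Over 30 lists, 327 alternative medians stayed within such intervals, 59 left them and 2 called medians changed sign: antigen presentation at -0.0029 without a filter, and metalloproteinases at -0.50 by the mean. The cause was not tested, except that without a filter many members near 0 enter. Without a filter the medians of the metalloproteinase and dendritic cell lists were 0. Of 180 named genes with a compared level, 1038 alternative values lay within the counting interval and 733 outside it, and none of those past 2-fold changed sign. The scalings shifted log2 ratios by at most 0.29, and a pseudocount cannot change the sign of a difference. The kept signs of these genes, Mmp9 included, were therefore largely fixed in advance. Depth limits folds of genes with few reads in 1 library, such as Ifit1 and Nos2, whose intervals are wide.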

Other observations

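The tests of admixed cells and of an innate stimulus, the centring by GC content and length, and the choice of chromosome 12 came only after the values they address had been seen.

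Genes of the unfolded protein and integrated stress responses were higher in the knockout as a group, 9 of 24 by at least 2-fold and 0 lower, with a median log2 ratio of 0.25 at percentile 99.98. Its members that differed most were these: the cystine transporter gene Slc7a11 was 10.7-fold higher (9.46 to 12.1), Trib3 9.50-fold, Atf3 14.9-fold and Chac1 3.81-fold. Slc7a11 and Atf3 also belong to other lists. The stress transcription factor gene Ddit3 was 3.08 and 3.82 (ratio interval 0.976 to 1.58), and the chaperone gene Hspa5 was 720 and 661. Of 21 genes of oxidative stress and iron handling 4 were higher and 1 lower, with a median of 0.02 at percentile 92.41, or 97.65 after centring by GC content. The ferritin gene Fth1 was 2.03-fold higher and the transferrin receptor gene Tfrc 2.52-fold lower. Immediate early genes gave 6 higher and 0 lower of 19, with a median of -0.07 and a mean of 0.44, and the median changed sign under every scaling and centring tried. The median stood at percentile 66.95, but at 99.88 (0.41) after centring by GC content and 99.7 (0.38) by GC content and length, and the mean at 99.82. Btg2 was 8.27-fold and Dusp2 4.28-fold higher.

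Hypoxia response genes gave 5 lower and 0 higher of 17, with a median of -0.26 at percentile 29.44 that turned positive with equal sums. Adm was 16.3-fold, Kdm3a 3.46-fold and Bnip3 3.18-fold lower. Lipid handling genes gave 3 lower and 1 higher of 18, with a median of -0.65 at percentile 0.25, or -0.28 at percentile 3.16 after centring by GC content. Pltp was lower, and the scavenger receptor gene Cd36 was 5.93-fold higher. The 22 cholesterol synthesis genes were all within 2-fold, with a median of -0.35 at percentile 9.73. Chosen after their values were seen, the complement genes C1qa and C1qb had 0 reads in the control and 0.0475 and 0.0950 in the knockout, and Ifnb1 had 0 reads in both libraries.

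The low medians of the oxidative phosphorylation, ribosomal protein and histone lists, most of whose genes were within 2-fold, run alongside the trend of the log2 ratio with transcript GC content and length. That trend was therefore removed. After centring, the medians were -0.70 for oxidative phosphorylation (percentile 0), -0.25 for ribosomal proteins (percentile 0.41) and -0.48 for histone genes (percentile 0.13). These values argue against the trend as the whole cause, although each median moved toward 0. For histone genes a difference in how weakly polyadenylated transcripts were captured stays open, as the lower members were clustered genes. The genotype stays open and untested, since 1 library per genotype cannot separate it from a difference between cultures. Levels come from whole cultures, so a different share of osteoclasts cannot be told apart from a change within cells.

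The higher interferon-stimulated genes kept a median of 3.16 after the same centring, above each random list, which argues against that trend. Admixed granulocytes, lymphocytes, erythroid or stromal cells would bring their own abundant transcripts. Markers of these and mast cells summed to 18.8 in the control and 40.1 in the knockout, against 154 and 1732 for the interferon-stimulated genes. The sums bear only on whether such cells carried these transcripts, not on whether a few of them acted on the others. Dendritic cell and monocyte markers were not in the sum. An innate stimulus present in only 1 of the 2 cultures may be a source. The inflammatory genes had a median of 1.96, with 12 of 20 higher and 3 lower by at least 2-fold, counts that the level filter partly set. The bootstrap interval of the median over list members ran from -0.03 to 3.03. With 1 culture per genotype such a stimulus cannot be told apart from an effect of the genotype. In whole cultures it cannot be told apart from a different share of osteoclasts and macrophages either.

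Genes of chromosome 12 were higher in the knockout than those of the other chromosomes: the median log2 ratio of 384 genes was 0.19 against -0.17 elsewhere, a ratio of 1.29, while the other 19 chromosomes lay between -0.28 and -0.07. Centring by GC content and length left 0.28, above each of 10000 random lists, which argues against that trend as the whole cause. Such a percentile was not particular to chromosome 12: after centring chromosome 3, at -0.097, lay below each random list, and chromosome 11, at 0.046, stood at percentile 99.92. Of the chromosome 12 genes 73.7% lay above the median of the other chromosomes, which argues against a few strongly changed genes, although a higher median by itself puts most genes there. The medians of 4 equal stretches ordered by position lay 0.27 to 0.41 above the others, which a few genes would not give either, and the lowest of them compares with at most 0.04 for any other chromosome. A candidate explanation is a gain of the chromosome in cells of 1 library. A loss in the control library would give the same ratio and was not tested, and no biological explanation from the design was tested. Among genes named above, Adam17, Rrm2 and Rsad2 (higher) and Ckb and Dnmt3a (lower) lie on chromosome 12, and their folds include this shift.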
